A study of Mus musculus with 12 samples.

How the data were processed

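RNA was measured in cultured fibroblast-like synoviocytes of mice by sequencing of poly(A)-enriched libraries with paired reads of 150 bases on a NovaSeq instrument, with 6 G of raw data per sample, per the labels' protocols. The series holds 12 libraries in 3 groups of 4. Groups and replicate numbers were taken from the sample titles. Treatments were taken from the labels: 5% sucrose water for 3 weeks (homeostasis), 1 mg/ml doxycycline in the same water for 3 weeks (inflammation), and the doxycycline course followed by its withdrawal (resolution). The time between withdrawal and harvest, the sex of the animals, the joints used and the culture passage are not given in the sources used here. The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

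The authors deposited 1 table of estimated read counts per gene symbol and library, not normalized, and the deposited column headers call the values total read counts. The reads were assigned on the mouse genome build GRCm38.p3, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. Of the deposited expected counts, 1.43% were not whole numbers (tolerance 0), which would arise where reads are shared between genes, so gene families with near-identical members were treated as uncertain. The table held 36930 entries. Of these, 13 carried no value and were left out, and 42 repeated entries over 34 symbols were summed with their partners, which left 36875 symbols. Counts were then rounded to whole numbers. Every value column was matched to a sample by its name. Within groups, the reduced chi-square of 2 libraries' counts over genes ran from 10.3 to 115.8, so no pair of libraries agreed within sampling noise, as repeated sequencing of 1 library would. All 12 were counted separately, although this check cannot tell separate animals from libraries of 1 culture. In homeostasis the value was 14.9 for libraries 3 and 4, 38.3 for 1 and 2, and 33.1 to 115.8 for pairs across them. In inflammation it was 10.3 for 1 and 2, 26.1 for 3 and 4, and 13.5 to 57.3 across. Subsets of libraries with a shared source can therefore not be excluded, and n = 4 may overstate the number of independent samples.

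Total counts per library ran from 18120745 to 34971537. A count of 0 in a library allows a level of up to 3 counts of its total, which is 0.086 to 0.166 CPM. Such limits cover counting error only, since no molecular identifiers are described.

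Genes were kept with the default expression filter of edgeR on the 3 groups, which left 15049 genes. Library sizes were scaled with the trimmed mean of M-values (TMM). The quasi-likelihood F test of edgeR was fitted with robust moderation to all 12 libraries with group as the only term, so that the 3 contrasts shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and every adjusted p of a gene below comes from this test. The fitted biological coefficient of variation was 18.6%. Levels are TMM-normalized CPM as mean ± SD with n = 4, and log2 fold changes carry their standard error (SE). Genes were called persistent when they passed in both comparisons against homeostasis in the same direction. They were called returned when they passed in inflammation, moved back between inflammation and resolution, and did not pass in resolution against homeostasis. They were called changed in resolution alone when they passed against both other groups in the same direction and did not pass in inflammation. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable tested genes.

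In all, 33 gene lists with 874 symbols were fixed before the data were examined, together with the design, the tests, the naming rule and the first set of alternative settings. Of the symbols, 851 were found as written, 20 under an older or alternative symbol taken from an NCBI RefSeq gene table (assembly GRCm38.p6, used for names and chromosomes only), and 3 were not matched. Lists were tested against all other genes with camera (limma) on log2 CPM with a preset correlation between genes of 0.01. P-values were adjusted over the lists of a comparison, and camera was run again with the correlation estimated from the data. The rotation test fry asked whether the members of a list moved on balance in 1 direction. The naming rule took Tnf in every library, the 10 largest rises and the 10 largest falls per comparison among genes that passed, had at least 5 CPM in the higher group and separated every library of one group from every library of the other, up to 4 members per list and comparison with the smallest adjusted p, and the 8 most changed genes per direction of each class of genes. Apoe, and Lyz2 where it is singled out, were chosen after their values were seen. Some genes that the rule takes are not reported here. Gene coordinates, GC content and transcript length came from GENCODE release M21 on GRCm38.

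The replicate numbers are shared between the groups, and no label says what they stand for. Deviations from the group means of equally numbered inflammation and resolution libraries were correlated over genes at r = 0.139, 0.126, 0.214 and 0.141, so by the rule fixed beforehand those 4 pairs were treated as paired, and the fit with replicate number as a block is given beside that comparison where it matters. Equally numbered pairs with homeostasis ran from -0.228 to 0.08, so some lay as far from 0 in the other direction. Only 4 of 12 libraries correlated best with a library of their own number in another group. The evidence for pairing is therefore weak.

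Because both comparisons against homeostasis use the same control libraries, unchanged groups were simulated 20 times from the homeostasis libraries, with the true level displaced by the error of the control mean, and the controls were also divided 2 and 2 in all 6 ways. The inflammation libraries (for returned genes) and the resolution libraries (for genes changed in resolution alone) were treated in the same way. The test was checked on simulated counts for 15049 genes with 200 genes changed. It recovered 18.5% of genes changed 1.5-fold, 76.1% changed 2-fold and 92.6% changed 4-fold for inflammation against homeostasis, with 1.6% false calls. For resolution against homeostasis these shares were 9.7%, 66.7% and 98.6% with 6.9% false calls, and for resolution against inflammation 16.4%, 65.6% and 94.2% with 7.8% false calls. Most changes of 1.5-fold were therefore missed in these simulations. Far more genes passed in the data than the 200 changed here, which makes the adjusted threshold less strict, so these shares may not carry over.

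Alternatives fixed before the data were examined were other size factors (RLE and upper quartile), DESeq2, limma-voom with quality weights, no low-count filter, a filter of 10 CPM in 4 libraries, fits with only the groups compared, the replicate block, stricter thresholds, and each library left out in turn. Chosen after seeing the data were the removal of genes on X, Y and the mitochondrial genome, homeostasis 1 and 2 or homeostasis 3 and 4 as the sole controls, offsets per library for GC content and transcript length, and the block fitted to the paired groups alone with and without those offsets. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.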

Results

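Gene expression was measured by sequencing of poly(A) RNA in cultured fibroblast-like synoviocytes, the connective tissue cells of the joint lining. The protocol given for all samples names mice with arthritis driven by tumour necrosis factor (TNF), although the homeostasis animals were given no doxycycline per the labels. Each of 3 groups held 4 libraries. The homeostasis group came from animals given 5% sucrose water for 3 weeks, and its sample descriptions call it WT. The inflammation group came from animals given 1 mg/ml doxycycline in sucrose water for 3 weeks, and the resolution group from animals whose doxycycline was stopped after those 3 weeks. The labels do not say whether all 3 groups shared a genotype. The stated purpose of the series was to learn how activated synoviocytes impair endothelial cells in the resolution phase. Homeostasis libraries 1 to 4 held 19908825, 34971537, 18352027 and 23367611 counts. The inflammation libraries held 21670149, 24145832, 20563912 and 23121710 counts, and the resolution libraries 18120745, 20807387, 21395822 and 20424321 counts. Levels are normalized CPM as mean ± SD, n = 4. Adjusted p-values of single genes come from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment.

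The groups separated on the first 2 principal components, which held 60.7% and 26.8% of the variance of the 500 most variable genes. On component 1, homeostasis lay at -42.6 to -35.5, inflammation at 8.0 to 11.9 and resolution at 26.3 to 30.4. Homeostasis 1 and 2 (-42.6 and -41.7) lay apart from homeostasis 3 and 4 (-35.7 and -35.5) there. Component 2 set inflammation (-26.7 to -25.8) apart from resolution (17.0 to 20.5). Log2 CPM of library pairs correlated across genes at 0.973 to 0.989 within groups and at 0.909 to 0.970 between groups.

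**Figure D1:**
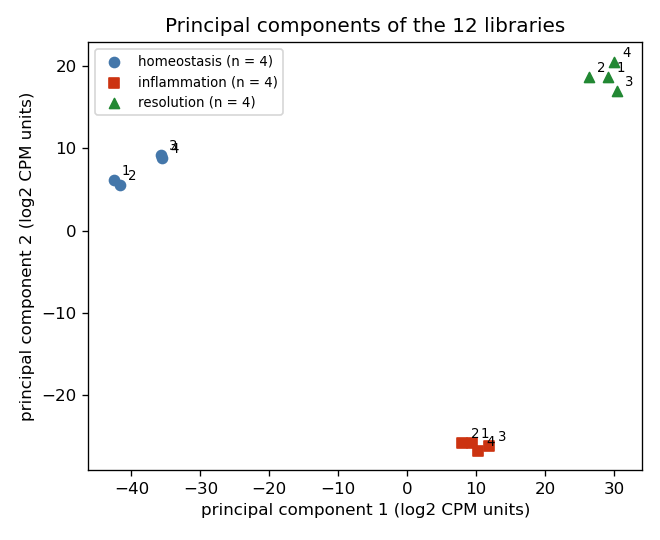
Scores of the 12 libraries on principal components 1 and 2 (log2 CPM units) from the 500 most variable tested genes. Each point is a library, numbered by replicate; the 3 groups of 4 do not overlap, and component 1 runs from homeostasis (-42.6 to -35.5) through inflammation to resolution (26.3 to 30.4).

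Tnf, named beforehand as a check of the labels, was lower in both doxycycline groups than in homeostasis and lowest in resolution. The mouse gene stood at 3.97 ± 2.20 CPM in homeostasis, 1.02 ± 0.518 CPM in inflammation and 0.308 ± 0.143 CPM in resolution (log2 fold change -1.96 ± 0.41 SE, edgeR adjusted p = 0.000986, and -3.66 ± 0.48 SE, adjusted p = 3.65e-06, each against homeostasis). With homeostasis 1 and 2 as the sole controls, a choice made after seeing the data, the first of these did not pass (-1.07, adjusted p = 0.0691). The check thus showed no higher Tnf after doxycycline. Which TNF sequence, if any, doxycycline switched on in the animals is not given in the sources used here, so the check cannot decide on the labels.

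Genes of the Y chromosome and Xist, the RNA that silences an X chromosome in female cells, divided the libraries in the same way as the controls and the doxycycline groups. Ddx3y (Y:1260771 to 1286629 on GRCm38, protein-coding) stood at 23.6 ± 1.82 CPM in homeostasis, summed to 3 counts over the inflammation libraries (a ratio of 664, counting interval 227 to 3220) and to 0 counts in resolution (at least 599-fold lower, from a limit of 3 counts over the group). Eif2s3y, Kdm5d and Uty had 0 counts in both doxycycline groups, at least 741-, 215- and 228-fold lower in inflammation. Xist (X:103460366 to 103483254, a long non-coding RNA) was at 10.8 ± 3.28 CPM in homeostasis, 110 ± 35.3 in inflammation and 174 ± 67.0 in resolution. Of the 5 tested sex-linked genes, 1 rose and 4 fell in both comparisons against homeostasis (the same counts adjusted over the list alone; camera adjusted p = 6.56e-06 and 0.000203, 0.00822 and 0.0277 with an estimated correlation), and 0 passed in edgeR between resolution and inflammation, where Xist had an unadjusted p of 0.0191 (camera adjusted p = 0.987, 0.991 with an estimated correlation). Xist passed there without inflammation 3 (0.86, edgeR adjusted p = 0.0403) and with the replicate number as a block (0.64, adjusted p = 0.0129). Every comparison against homeostasis was therefore also a comparison of libraries with Y-linked transcripts and libraries almost without them.

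**Figure D2:**
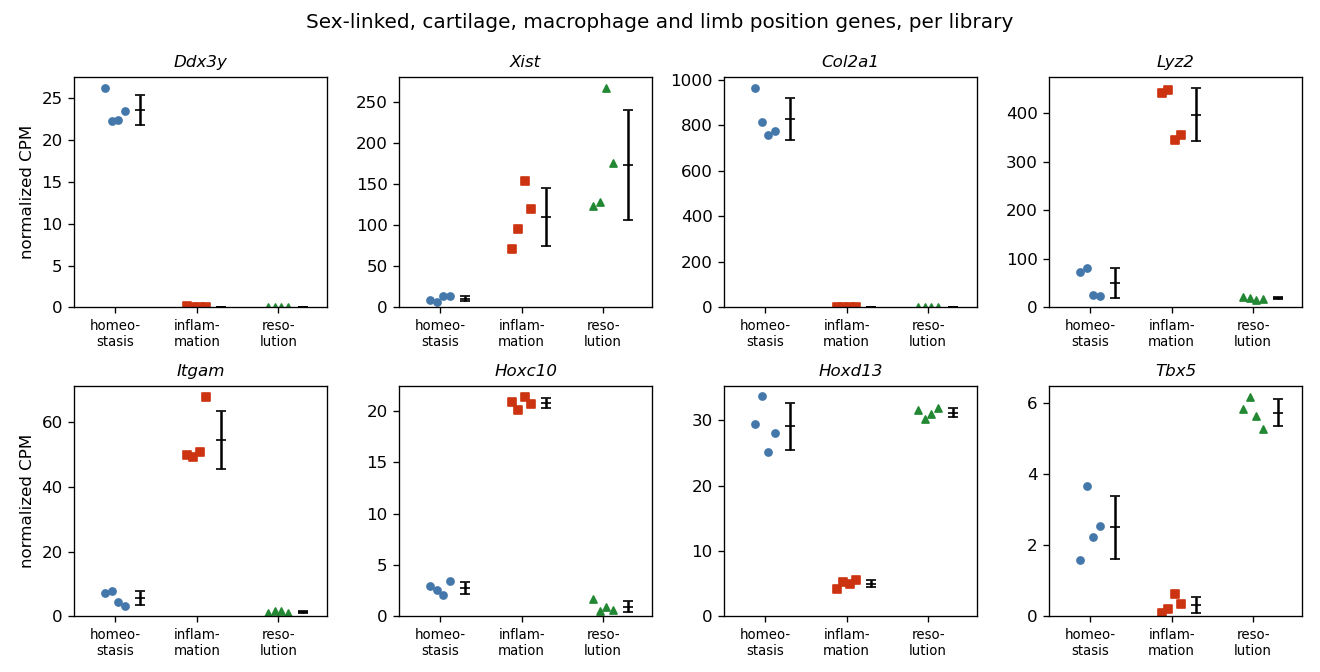
Normalized CPM per library (points) with mean ± SD (bar to the right of each group, n = 4) of sex-linked, cartilage, macrophage and limb position genes. Ddx3y and Col2a1 are high in the 4 homeostasis libraries alone, Xist is higher in both doxycycline groups, Lyz2 and Itgam are higher in inflammation, Hoxc10 is highest in inflammation, and Hoxd13 and Tbx5 are lowest there.

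Inflammation against homeostasis compared cultured synoviocytes after the doxycycline course with the controls, which the sample descriptions call WT. Interferon-stimulated genes, complement genes and markers of macrophages rose, while genes of the cell cycle and of the integrated stress response and markers of chondrocytes fell. For the interferon and chondrocyte lists the adjusted p was 0.21 and 0.0766 with an estimated correlation. Arg1, the urea cycle enzyme arginase (10:24915221 to 24927484), went from 0.112 ± 0.103 to 52.0 ± 19.1 CPM (log2 fold change 8.60 ± 0.48 SE, edgeR adjusted p = 1.61e-10). Mmp8, a collagenase (9:7558456 to 7568485), rose from 0.389 ± 0.331 to 27.4 ± 2.49 CPM (6.08 ± 0.33 SE, adjusted p = 1.01e-10). Col2a1, the main cartilage collagen (15:97975602 to 98004695), fell from 828 ± 93.9 to 2.62 ± 0.50 CPM (-8.30 ± 0.22 SE, adjusted p = 9.75e-16). In all, 5602 of 15049 genes passed, 2852 higher and 2750 lower, of which 1332 and 750 differed at least 2-fold. Upper-quartile factors gave 3297 higher and 2151 lower.

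Of 36 tested interferon-stimulated genes, 32 rose and 0 fell (34 and 0 adjusted over the list alone; camera adjusted p = 9.45e-17, adjusted p = 0.21 with an estimated correlation). Ifit1, which binds foreign RNA (19:34640871 to 34650009), was at 5.85 ± 4.87 CPM in homeostasis and 99.5 ± 8.19 CPM in inflammation (4.10 ± 0.50 SE, edgeR adjusted p = 6.45e-05). Its homeostasis levels ran from 1.62 to 12.3 CPM, below every doxycycline library. Trim30a, Sp100 and the large GTPase gene Gvin1 also rose (log2 fold changes 3.78, 2.81 and 4.92), Gvin1 belonging to a family of similar genes whose reads are uncertain. Of 24 antigen presentation genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00047, adjusted p = 0.497 with an estimated correlation). B2m, the light chain of class I molecules, went from 313 ± 60.8 to 632 ± 17.2 CPM (1.02 ± 0.14 SE, adjusted p = 1.17e-05). With homeostasis 3 and 4 as the sole controls, chosen after seeing the data, the antigen presentation list did not pass (adjusted p = 0.31). Of 18 complement genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 7.22e-06, 0.0189 with an estimated correlation). Cd55, which protects cells from complement, rose by log2 2.32 ± 0.17 SE, and Cfd, a protease of the alternative pathway, fell by 5.57.

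Of 19 tested markers of macrophages, 18 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.03e-09, 0.0021 with an estimated correlation). Fcgr3 went from 1.76 ± 0.445 to 22.5 ± 4.77 CPM and Itgam from 5.64 ± 2.25 to 54.4 ± 8.91 CPM (3.64 ± 0.24 and 3.26 ± 0.24 SE, edgeR adjusted p = 1.59e-09 and 4.21e-09). Lyz2, the lysozyme of myeloid cells, was at 50.9 ± 30.8, 398 ± 55.1 and 18.6 ± 2.26 CPM in homeostasis, inflammation and resolution. Mmp12, Mmp8 and the lysosomal protease Ctss rose among the matrix-degrading proteases, with log2 fold changes of 4.80, 6.08 and 3.64. Over the 30 tested proteases 11 rose and 6 fell (11 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0948, 0.497 with an estimated correlation). It passed with homeostasis 1 and 2 as the sole controls (0.0355) and with fry (0.000513), which asks whether members moved on balance in 1 direction. Ccl6 and Pf4, chemokines also made by myeloid cells, rose by log2 6.59 ± 0.75 and 4.40 ± 0.36 SE.

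Of 30 targets and regulators of NF-kB, the transcription factor downstream of TNF, 4 rose and 16 fell (the same adjusted over the list alone; camera adjusted p = 0.0389, adjusted p = 0.64 with an estimated correlation). Tnip1 and Ptx3 fell (-1.09 ± 0.16 and -0.83 ± 0.13 SE), whereas Ptgs2, the inducible prostaglandin synthase, went from 408 ± 120 to 1229 ± 162 CPM (1.59 ± 0.19 SE, edgeR adjusted p = 3.24e-06). The list did not pass without homeostasis 3 (adjusted p = 0.124), homeostasis 4 (0.0883) or inflammation 2 (0.055), nor with homeostasis 1 and 2 as the sole controls (0.655) or with fry (0.079). Of 37 cytokines and chemokines, 12 rose and 7 fell (14 and 8 adjusted over the list alone; camera adjusted p = 0.152, 0.685 with an estimated correlation), and the list passed with homeostasis 1 and 2 as the sole controls (0.00221). Ccl8 and Ccl7, which attract monocytes, rose (3.22 and 0.96), and Ccl20 and Cxcl12 fell (-3.08 and -1.43).

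All 38 proliferation genes that passed, of 40 tested, fell (38 adjusted over the list alone; camera adjusted p = 1.65e-25, 0.00233 with an estimated correlation). The mitotic kinase gene Plk1 went from 135 ± 5.40 to 31.6 ± 3.58 CPM (-2.09 ± 0.14 SE, edgeR adjusted p = 1.96e-09). Among 22 senescence-associated genes, 8 rose and 6 fell (the same adjusted over the list alone), with Cdkn2a up (1.89 ± 0.15 SE) and Lmnb1 down (-2.29 ± 0.14 SE), and the list did not pass (camera adjusted p = 0.662, 0.765 with an estimated correlation). Of 29 genes of the integrated stress response, 24 fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 6.46e-10, 0.0289 with an estimated correlation), among them the serine synthesis enzyme gene Psat1 (-1.80 ± 0.12 SE). The unfolded protein response (11 of 21 fell, 1 rose, the same adjusted over the list alone) and the glycolysis and hypoxia list (15 of 32 fell, 2 rose; 18 and 2 adjusted over the list alone) were also lower (camera adjusted p = 0.00047 and 0.0012; adjusted p = 0.144 and 0.466 with an estimated correlation). The glycolysis and hypoxia call was lost with homeostasis 1 and 2 as the sole controls (0.095). Of 32 oxidative stress genes, 17 rose and 6 fell (18 and 6 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.216 with an estimated correlation), with the quinone reductase Nqo1 at 57.2 ± 12.1 and 267 ± 52.0 CPM.

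Markers of chondrocytes, skeletal muscle cells and Schwann cells were lower in inflammation. Of 11 chondrocyte markers, 7 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.000125, adjusted p = 0.0766 with an estimated correlation). Of 10 skeletal muscle markers, 7 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0017, 0.0319 with an estimated correlation), and of 10 Schwann cell markers 6 fell and 0 rose (the same adjusted over the list alone; 0.000435 and 0.0191). Sox10, a glial transcription factor, went from 12.3 ± 1.38 to 3.87 ± 0.355 CPM. The contractile and TGF-beta-induced list was higher (12 rose and 1 fell of 28, the same adjusted over the list alone; camera adjusted p = 0.00287, adjusted p = 0.376 with an estimated correlation), with Lmod1 at 33.2 ± 9.05 and 101 ± 13.4 CPM. Limits of this comparison are the sex-linked difference, the description of the controls as WT and the spread of the controls. Sex, genotype or cell source, where they differ, cannot be told apart from the doxycycline course here. The biological coefficient of variation was 21.8% in the controls against 14.9% in inflammation. Offsets for GC content and transcript length, chosen after seeing the data, gave 6679 calls, 2972 higher and 3707 lower, of which 4963 were among the 5602.

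Resolution against homeostasis asked what remained different after doxycycline was stopped, the question in the title of the series. Interferon-stimulated and antigen presentation genes were higher than in homeostasis, and cell-cycle and matrix genes were lower. The adjusted p of the interferon, antigen presentation and matrix lists was 0.298, 0.438 and 0.426 with an estimated correlation. Ifit1 stood at 221 ± 50.9 CPM (log2 fold change 5.25 ± 0.52 SE, edgeR adjusted p = 5.68e-06), B2m (2:122147686 to 122153083) at 1350.3 ± 135 CPM (2.11 ± 0.14 SE, adjusted p = 4.79e-10) and Hgf, hepatocyte growth factor, at 92.1 ± 17.3 CPM against 19.1 ± 2.98 CPM (2.27 ± 0.16 SE, adjusted p = 7.62e-10). Col1a1, the main fibrillar collagen, fell from 9560 ± 984 to 3118 ± 1181 CPM (-1.62 ± 0.19 SE, adjusted p = 1.17e-06). In all, 8025 genes passed, 4137 higher and 3888 lower, of which 2289 and 1241 differed at least 2-fold.

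Of 36 interferon-stimulated genes, 34 rose and 0 fell (34 and 1 adjusted over the list alone; camera adjusted p = 4.51e-15, adjusted p = 0.298 with an estimated correlation). Oas2, a sensor of double-stranded RNA, went from 0.404 ± 0.422 to 25.8 ± 2.36 CPM (5.98 ± 0.37 SE, edgeR adjusted p = 1.52e-10), and Sp100 and Slfn5 rose by log2 4.61 ± 0.23 and 5.14 ± 0.33 SE. Of 24 antigen presentation genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 3.25e-05, adjusted p = 0.438 with an estimated correlation). The class I heavy chain gene H2-D1, a member of a near-identical family and so uncertain, was at 249 ± 97.9 and 896 ± 123 CPM. Of 18 complement genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00326, adjusted p = 0.0951 with an estimated correlation), with Serping1, the C1 inhibitor, at 991 ± 137 against 162 ± 31.5 CPM. Macrophage markers went the other way: 13 of 19 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.000118, 0.0219 with an estimated correlation). Tyrobp, one of them, fell by 3.66 on the log2 scale, and the scavenger receptor gene Marco, outside the list, by 6.98.

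Among 52 tested secreted factors acting on endothelial cells, 18 rose and 13 fell (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.394, 0.546 with an estimated correlation), while in inflammation 22 rose and 11 fell (24 and 12 adjusted over the list alone; camera adjusted p = 0.0592, 0.21 with an estimated correlation). The inflammation result passed without homeostasis 2 (adjusted p = 0.0422), without inflammation 1 (0.0494) and with GC and length offsets (0.0386), and with fry the list passed in both inflammation and resolution (6.94e-05 and 4.03e-05). Igf1 went from 3.45 ± 0.713 CPM in homeostasis to 15.4 ± 0.610 in inflammation and 25.1 ± 2.88 in resolution (2.85 ± 0.17 SE in resolution, edgeR adjusted p = 8.63e-11), and Fgf10 from 3.78 ± 0.645 to 15.4 ± 1.70 and 23.9 ± 3.61 CPM (2.65 in resolution). With GC and length offsets, chosen after seeing the data, the log2 fold changes in resolution were smaller for Igf1, Fgf10 and Hgf (1.87, 2.02 and 1.59), and all 3 genes passed. Bmp4 fell by 3.06 and Thbs4, an extracellular thrombospondin, by 2.18 on the log2 scale in resolution. Of 37 cytokines and chemokines, 12 rose and 16 fell (12 and 17 adjusted over the list alone; camera adjusted p = 0.769, 0.91 with an estimated correlation). Ccl11, the eosinophil chemoattractant eotaxin (11:82057823 to 82062955), was at 4.53 ± 1.02, 6.12 ± 1.86 and 81.1 ± 18.2 CPM in the 3 groups (4.15 ± 0.24 SE in resolution, adjusted p = 6.55e-11), and Tslp at 8.99 ± 2.39, 8.72 ± 2.04 and 43.6 ± 9.37 CPM. Of 30 NF-kB targets and regulators 7 rose and 16 fell (8 and 16 adjusted over the list alone; camera adjusted p = 0.103, 0.782 with an estimated correlation), and the list passed without homeostasis 1 (0.0371), without homeostasis 2 (0.0395), with homeostasis 3 and 4 as the sole controls (0.00181) and with fry (0.0407).

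**Figure D3:**
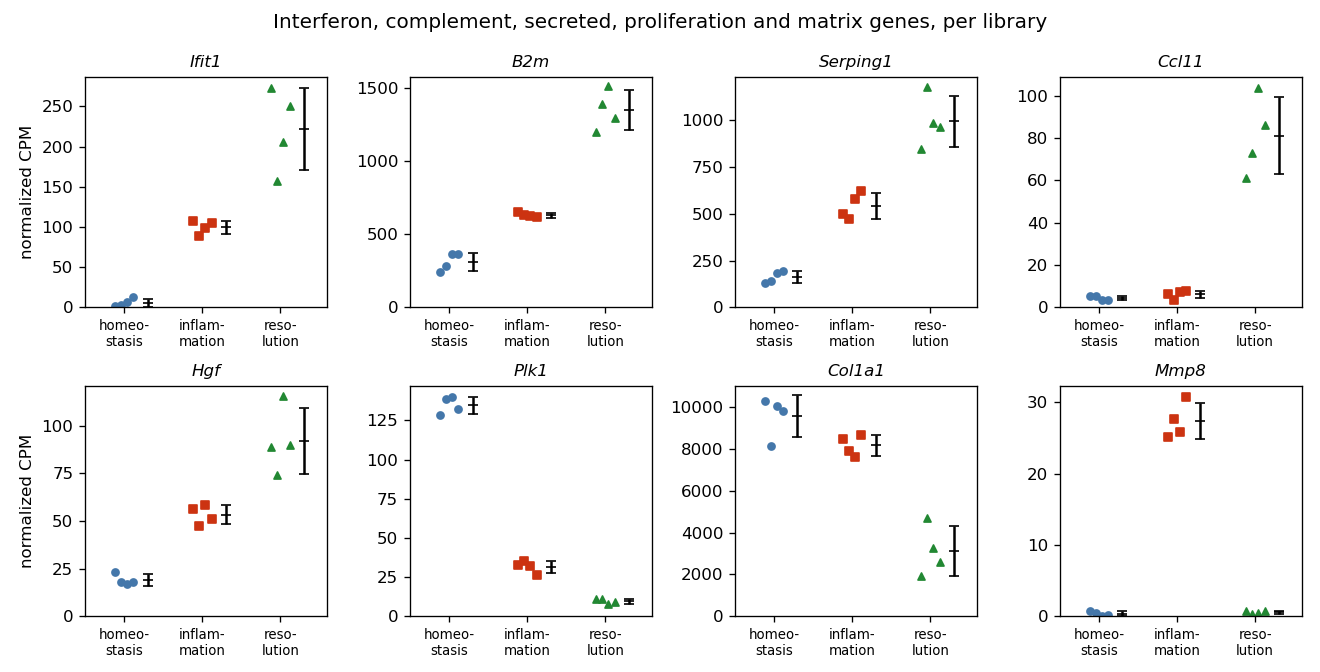
Normalized CPM per library (points) with mean ± SD (bar to the right of each group, n = 4) of interferon, complement, secreted, cell-cycle and matrix genes. Ifit1, B2m, Serping1 and Hgf are higher in inflammation than in homeostasis and have their highest means in resolution, Ccl11 is high in resolution alone (81.1 ± 18.2 CPM), Plk1 falls from 135 to 31.6 and 9.67 CPM, and Mmp8 is high in inflammation alone.

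Of 40 proliferation genes, 39 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 4.09e-26, 0.00427 with an estimated correlation). Plk1 stood at 9.67 ± 1.64 CPM (-3.80 ± 0.15 SE, edgeR adjusted p = 1.42e-12), and the replication helicase gene Mcm5 fell from 170 ± 18.7 to 18.1 ± 1.84 CPM. Of 53 extracellular matrix genes, 34 fell and 8 rose (36 and 9 adjusted over the list alone; camera adjusted p = 8.56e-05, adjusted p = 0.426 with an estimated correlation). Col6a2 and Nid2 fell (-2.14 ± 0.16 and -1.88 ± 0.14 SE), and the proteoglycan Dcn rose from 161 ± 66.1 to 897 ± 144 CPM (2.48, and 1.54 with GC and length offsets). Of 21 unfolded protein response genes, 15 fell and 1 rose, and of 29 integrated stress response genes 23 fell and 0 rose (both the same adjusted over the list alone; camera adjusted p = 2.84e-05 and 6.6e-08; adjusted p = 0.0951 and 0.0661 with an estimated correlation). The disulfide isomerase gene Pdia6 fell from 1599 ± 151 to 569 ± 79.2 CPM. The glycolysis and hypoxia list fell (22 of 32 fell and 2 rose, the same adjusted over the list alone; camera adjusted p = 0.000323, adjusted p = 0.426 with an estimated correlation). Chondrocyte and skeletal muscle markers were lower (7 of 11 fell and 1 rose, 8 and 1 adjusted over the list alone; 7 of 10 fell and 0 rose, the same adjusted over the list alone; camera adjusted p = 0.00243 and 0.00242; adjusted p = 0.199 and 0.0581 with an estimated correlation).

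Limits of this comparison are the sex-linked difference, the description of the controls as WT and a trend with base composition. Sex, genotype or cell source, where they differ, cannot be told apart from the doxycycline course and its withdrawal. Higher genes had a median GC content of 44.5% against 52.5% in lower genes. Across genes, log2 fold changes correlated with GC content at a Spearman coefficient of -0.40 (-0.21 in inflammation). With GC and length offsets, which brought this coefficient to -0.01, 7991 genes passed, 3944 higher and 4047 lower, 6230 of them among the 8025.

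Resolution against inflammation asked what changed after withdrawal, and both groups were almost without Y-linked transcripts (0 counts per gene, but 3 of Ddx3y in inflammation). Macrophage markers fell, proliferation genes fell further, matrix genes fell and 13 of 36 interferon-stimulated genes rose, and genes that mark position along the limbs changed in both directions. For the matrix and interferon lists the adjusted p was 0.272 and 0.662 with an estimated correlation. Arg1 fell from 52.0 ± 19.1 to 0.339 ± 0.247 CPM (log2 fold change -7.26 ± 0.43 SE, edgeR adjusted p = 4.85e-10) and Mmp8 from 27.4 ± 2.49 to 0.583 ± 0.226 CPM (-5.54 ± 0.32 SE, adjusted p = 3.66e-10). Ccl11 rose by 3.73 ± 0.24 SE (adjusted p = 9.98e-10) and Oas2 by 2.74 ± 0.29 SE (adjusted p = 1.54e-06). In all, 2431 genes passed, 1282 higher and 1149 lower, of which 318 and 488 differed at least 2-fold. Upper-quartile factors turned the split to 1011 higher and 1318 lower. With the replicate number as a block in a fit of these 8 libraries, added after seeing the data, 4808 genes passed, 2585 higher and 2223 lower, of which 2393 were among the 2431. The same 8 libraries without the block gave 3067, and the block in the fit of all 12 libraries gave 1898, 948 higher and 950 lower. Limma-voom with quality weights gave 7405, 4011 higher and 3394 lower.

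Of 19 macrophage markers, 18 fell and 0 rose (the same adjusted over the list alone; camera adjusted p = 1.11e-26, 2.7e-05 with an estimated correlation). Itgam went from 54.4 ± 8.91 to 1.45 ± 0.295 CPM and Tyrobp, a signalling adaptor of myeloid cells, from 11.7 ± 2.95 to 0.118 ± 0.0792 CPM (-5.22 ± 0.27 and -6.56 ± 0.37 SE, edgeR adjusted p = 1.51e-10 and 3.66e-10). Marco, outside this list and without a call in inflammation, fell from 13.9 ± 3.99 to 0.118 ± 0.0940 CPM. Of 30 proteases, 10 fell and 2 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.000906, adjusted p = 0.258 with an estimated correlation), with Mmp12 and Ctss at log2 fold changes of -3.73 and -3.86.

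Of 28 tested limb position genes, 8 rose and 9 fell (8 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.481, 0.811 with an estimated correlation). Hoxd13, a gene of the distal limb, was at 29.1 ± 3.58, 4.99 ± 0.556 and 31.2 ± 0.742 CPM in homeostasis, inflammation and resolution (2.64 ± 0.15 SE between the last 2, edgeR adjusted p = 3.66e-10). Tbx5, a forelimb transcription factor, was at 2.50 ± 0.874, 0.322 ± 0.236 and 5.72 ± 0.375 CPM. Hoxc10, active in the hindlimb, went the other way, at 2.78 ± 0.610, 20.7 ± 0.514 and 0.954 ± 0.528 CPM (-4.45 ± 0.27 SE, adjusted p = 4.85e-10), as did Hoxc11 (-4.39 ± 0.26 SE). In inflammation against homeostasis 12 limb genes rose and 7 fell (14 and 7 adjusted over the list alone; camera adjusted p = 0.47, 0.714 with an estimated correlation), and in resolution against homeostasis 6 rose and 5 fell (the same adjusted over the list alone; 0.87 and 0.924).

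Of 36 interferon-stimulated genes, 13 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 3.79e-05, adjusted p = 0.662 with an estimated correlation), and of 24 antigen presentation genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00156, adjusted p = 0.662 with an estimated correlation). B2m rose by 1.09 ± 0.14 SE and Sp100 by 1.80 ± 0.19 SE, while Ifit1 did not pass (1.15 ± 0.43 SE, edgeR adjusted p = 0.0909). It passed without homeostasis 1 (adjusted p = 0.00881), without homeostasis 4 (0.00877) and with the replicate block in all 12 libraries (0.0371). With fry the interferon and antigen presentation lists did not pass (adjusted p = 0.169 and 0.113). Of 40 proliferation genes, 32 fell and 1 rose (36 and 1 adjusted over the list alone; camera adjusted p = 5.52e-27, 0.00188 with an estimated correlation). Of 53 matrix genes, 18 fell and 0 rose (20 and 1 adjusted over the list alone; camera adjusted p = 2.79e-07, adjusted p = 0.272 with an estimated correlation), among them Col1a2 and Col1a1 (-1.15 ± 0.16 and -1.39 ± 0.19 SE). Lower were also the contractile list (12 of 28 fell and 2 rose, 15 and 2 adjusted over the list alone), cholesterol and fatty acid synthesis (15 of 30 fell and 0 rose, 18 and 0 adjusted over the list alone) and the unfolded protein response (10 of 21 fell and 0 rose, the same adjusted over the list alone). Their camera adjusted p was 6.23e-05, 1.5e-06 and 0.000227, and their adjusted p was 0.258, 0.0579 and 0.228 with an estimated correlation. Tgfbi, Mvd and Pdia6 were examples (-1.19, -0.85 and -0.69). Of 52 secreted factors acting on endothelial cells, 12 rose and 7 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.987, 0.991 with an estimated correlation), with Hgf and Sema3c higher (0.79 ± 0.15 and 0.88 ± 0.19 SE) and Sfrp1 lower (-1.83 ± 0.19 SE). Sublining fibroblast markers, 8 of 22 up and 3 down (9 and 3 adjusted over the list alone), did not pass (camera adjusted p = 0.0692, 0.258 with an estimated correlation), but passed with the block in the 8 libraries (0.0362, and 0.00879 with offsets), with GC and length offsets (0.037), without resolution 3 (0.039) or 4 (0.0437) and with fry (0.00112). With the block in all 12 libraries the list did not pass.

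Glycolysis and hypoxia genes were lower as a list with 2 of 32 down and 1 up (1 and 1 adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.712 with an estimated correlation). That call was lost without inflammation 4 (0.0857), without resolution 3 (0.117) with GC and length offsets (0.0797) and with fry (0.204). Schwann cell markers were higher, with 5 of 10 up and 0 down (6 and 0 adjusted over the list alone; camera adjusted p = 0.00893, adjusted p = 0.0997 with an estimated correlation). This was lost without homeostasis 1 (0.0508), 2 (0.0681), 3 (0.053) or 4 (0.0694) without resolution 2 (0.121), and with homeostasis 1 and 2 (0.156) or 3 and 4 (0.0706) as the sole controls. S100b, a calcium-binding protein of glia, went from 1.18 ± 0.154 to 4.47 ± 1.03 CPM.

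The number of calls in this comparison depended on single libraries. It was 1443 without inflammation 1, 1351 without inflammation 2, 1584 without resolution 1, 1299 without resolution 3 and 1242 without resolution 4, but 4191 without resolution 2, whose counts correlated with GC content relative to the other libraries at 0.10 where resolution 1, 3 and 4 were at -0.43, -0.52 and -0.51. Fold changes correlated with GC content across genes at -0.47, and 2402 genes passed with GC and length offsets, 1781 of them among the 2431.

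**Figure D4:**
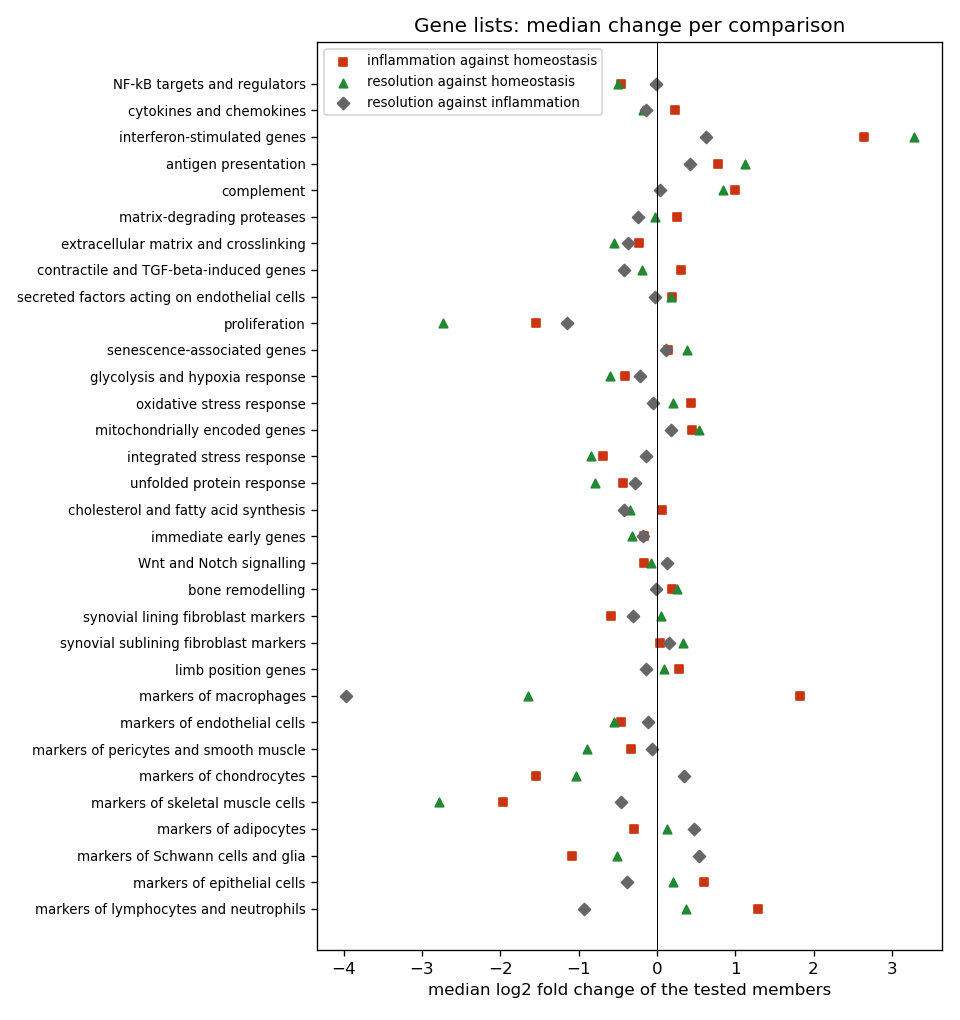
Median log2 fold change of the tested members of 32 gene lists fixed before the data were examined (horizontal axis), with 1 marker per comparison; sex-linked genes are left out because several had 0 counts in a group. Interferon-stimulated genes lie furthest right against homeostasis (medians 2.65 and 3.28), proliferation genes lie left in all 3 comparisons, and macrophage markers change side between inflammation (1.82) and resolution (-1.64).

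Across the 3 comparisons, 4668 genes were persistent (2378 higher, 2290 lower), 261 returned (170 that had risen, 91 that had fallen) and 829 changed in resolution alone (484 higher, 345 lower), while 113 passed in opposite directions against homeostasis. The persistent split was 2687 higher and 1875 lower with upper-quartile factors and turned to 2405 and 3014 with GC and length offsets, and the returned split was 202 and 67, and 202 and 168. With limma-voom and quality weights the persistent split was 2742 higher and 2782 lower. The returned split turned to 332 that had risen and 365 that had fallen, of 697. Persistent genes were 83.3% of the inflammation calls. Between inflammation and resolution, 988 of them moved further from homeostasis, 86 moved closer and 3594 had no call. Genes that moved back far enough to lose their call in resolution are outside this class by definition, which lowers the number that moved closer. Fold changes between these 2 groups also followed GC content (-0.47). Persistent rises included Gvin1, Ifi44, Gsta3 and Ifit1, and persistent falls included Col2a1, the matrix protein Coch (-3.29 and -3.25) and the imprinted RNA H19 (-3.22 and -4.94). Gsta3, a glutathione transferase of a family with similar members, was at 0.689 ± 0.147, 15.6 ± 3.58 and 14.6 ± 1.88 CPM. With GC and length offsets Gvin1 was at log2 4.86 in resolution, against 5.77. Genes that returned included Arg1, Mmp8, Pf4 and the Fc receptor gene Fcgr2b among those that had risen and Hoxd13 among those that had fallen. Without resolution 3, Arg1 also passed against homeostasis in resolution (1.77, edgeR adjusted p = 0.0306) and left this class. So did Fcgr2b with GC and length offsets (-0.63, adjusted p = 0.0164) and Pf4 with homeostasis 3 and 4 as the sole controls (-0.85, adjusted p = 0.0388). Genes changed in resolution alone included Ccl11, the peptide hormone gene Cck (304 ± 12.4 against 58.4 ± 26.9 CPM) and Tslp among the rises and Marco and Irg1, an enzyme gene of activated myeloid cells, among the falls. Ccl11 passed in inflammation without inflammation 2 (0.64, adjusted p = 0.0278), and Cck did without homeostasis 4 (0.73, adjusted p = 0.00294) and with GC and length offsets (0.46, adjusted p = 0.0395).

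The persistent class compares both groups with the same controls. Simulated unchanged groups gave 0 persistent genes on average over 20 draws (0 returned and 0 changed in resolution alone). Both simulated comparisons against homeostasis had 0 calls on average, so classes that need 2 calls were bound to be empty. How many genes shared controls add where many genes differ was not simulated. Independent lists would share 784 higher and 710 lower genes, and with the controls divided 2 and 2 the persistent class held 2602 to 3836 genes. For returned genes, 2 independent lists would share 218 and 234 genes, and for resolution alone 352 and 297. These overlaps leave out the condition of no call in the remaining comparison, so they are not chance sizes of these classes. With the inflammation libraries divided 2 and 2, 106 to 133 genes returned. With the resolution libraries so divided, 162 to 624 genes changed in resolution alone. Log2 fold changes of inflammation and resolution against homeostasis correlated across genes, which are not independent replicates, at r = 0.78, with 82.1% of genes on the same side of 0. Simulated unchanged groups gave r = 0.435 and 66.6%, and divided controls gave r = 0.609 to 0.711. The covariance was 0.716 against a simulated 0.032. The difference of 0.684 estimates what both groups share in their distance from homeostasis. It includes the sex-linked difference and any other that sets the controls apart. Resolution alone held 493 genes without inflammation 1, 446 without inflammation 2, 492 without resolution 1, 353 without resolution 3, 339 without resolution 4 and 1645 without resolution 2. Upper-quartile factors turned its split to 343 higher and 437 lower genes, against 484 and 345.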

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

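The tests of libraries with an opposite sex-linked pattern, of macrophage markers, of other cell type markers, of single-cell libraries, of hindlimb genes and of offsets on limb genes were chosen after the results were seen, and the split counts and the X-linked genes before.

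Y-linked transcripts were present in the 4 homeostasis libraries and at 0 to 3 counts in total per gene in each doxycycline group, while Xist was higher in both. Source animals of different sex are a candidate explanation: of 4 X-linked genes that escape inactivation, Kdm6a, Eif2s3x and Ddx3x rose in both comparisons against homeostasis and Kdm5c did not pass, with medians of 0.87 and 1.4 on the log2 scale (0.59 and 0.86 with GC and length offsets). Eif2s3x and Ddx3x also rose in resolution against inflammation (0.59 and 0.47, edgeR adjusted p = 0.049 and 0.0438), where Kdm6a and Kdm5c did not pass. Those groups share the sex-linked pattern, so the X-linked genes did not follow it alone and cannot decide the question. Sex-dependent expression of autosomal genes cannot be told apart from the doxycycline course, because 0 libraries had the opposite pattern to their group. The design gives no sex, so no biological explanation of this pattern was tested beyond these values.

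Macrophage markers were higher in inflammation than in both other groups. Macrophages in those cultures may be a source, but these values cannot decide it. Of 19 tested markers, 13 were higher in every inflammation library than in each of the other 8. The share was 2.3% of all tested genes (353 of 15049) and 0.2% by chance. That number fell short of the 15 set for that explanation, a cutoff also chosen after the results were seen. The count restates the pattern, and expression of the markers by fibroblasts could give it as well. Lyz2, the most abundant of them, was at 344 to 448 CPM in inflammation and 15.8 to 81.5 CPM elsewhere. Markers of other cell types did not all rise together, as 6 of 8 such lists had a median below 0 in inflammation against homeostasis, with epithelial (4 tested, 0.60) and lymphocyte and neutrophil markers (3 tested, 1.30) above 0. This cannot decide whether the share of the main cell type was lower. Each cell type can change by itself, and added macrophages would lower the shares of all others together. Expression of the markers by the fibroblasts themselves, after doxycycline, stays open and cannot be told apart from added macrophages, since 0 libraries came from single cells.

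Limb position genes differed between inflammation and resolution, some in each direction. The trend with GC content and transcript length is argued against as the cause, because 17 of 17 called limb genes kept their call and direction with the offsets and the replicate block together. Cultures from different limbs or joints may be a source: 3 of 4 hindlimb genes (Pitx1, Hoxc10 and Hoxc11) fell in resolution against inflammation and Tbx5, a forelimb gene, rose, but Tbx4, active in the hindlimb, did not pass (0.12 ± 0.15 SE). This cannot be told apart from an effect of withdrawal on these genes, since the joints used are not given in the sources used here.

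Some genes passed against homeostasis in opposite directions in inflammation and resolution, and each also passed in the direct contrast of those groups. The log2 fold changes in that contrast, with those of inflammation and of resolution against homeostasis after them, were as follows. Tbx5 had 4.16 (-2.98 and 1.17), Hoxd11 2.68 (-2.28 and 0.40) and Hoxd10 2.66 (-2.16 and 0.50). Hoxc11 had -4.39 (3.09 and -1.29), Hoxc10 -4.45 (2.89 and -1.56) and Pitx1 -3.11 (0.55 and -2.56). Among myeloid genes, Tyrobp had -6.56 (2.90 and -3.66), Itgam -5.22 (3.26 and -1.96), Hcls1 -4.85 (1.20 and -3.65), Cfp -4.11 (2.49 and -1.62) and Lyz2 -4.42 (2.96 and -1.46). Tgfbi had -1.19 (0.79 and -0.39), Tgfb3 -1.17 (0.57 and -0.60) and Ptn -2.25 (1.09 and -1.15).

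The weaker of the calls against homeostasis rested on single libraries for 4 of these genes. Hoxd11 in resolution did not pass without homeostasis 1 (adjusted p = 0.0894), homeostasis 4 (0.064), resolution 3 (0.0597) or resolution 4 (0.0544). Hoxd10 in resolution did not pass without homeostasis 2 (0.0557), homeostasis 3 (0.0742), resolution 1 (0.0563), resolution 3 (0.0887) or resolution 4 (0.0507). Tgfbi in resolution did not pass without homeostasis 1 (0.05), homeostasis 2 (0.104), resolution 1 (0.0776) or resolution 4 (0.101). Pitx1 in inflammation did not pass without homeostasis 2 (0.0573), homeostasis 3 (0.0906), inflammation 1 (0.0797) or inflammation 3 (0.0636). With GC and length offsets, chosen after seeing the data, the resolution calls of Hoxd11 (-0.09, adjusted p = 0.635), Hoxd10 (0.0749), Tgfbi (0.352) and Tgfb3 (0.0534) were lost. With homeostasis 3 and 4 as the sole controls, also chosen after seeing the data, those of Hoxd11 (0.117), Tgfbi (0.278) and Tgfb3 (0.0665) in resolution and of Pitx1 in inflammation (0.0931) were lost. With homeostasis 1 and 2 instead, those of Hoxd10 in resolution (0.13) and of Tgfb3 in inflammation (0.114) were lost.

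In 398 groups of 4 values, 23 held a library far from the other 3 (above the 95% critical value of Dixon's gap ratio), where chance gives about 1 in 20 groups, or 19.9. In resolution 2, Col2a1 was at 3.92 CPM (others 2.27 and more), Acan at 0.14 (others 0), Trim30a at 17.3 (others 24.6 and more), Hcls1 at 1.03, Cxcl12 at 21.2, Thbs4 at 143 and Ndrg1 at 14.8 CPM. In resolution 3, Mmp12 was at 10.5 CPM, and in resolution 4 Loxl4 was at 41.6 CPM. In inflammation 1, Ddx3y was at 0.137 CPM (others 0) and Hyou1 at 474. In inflammation 3, Igf1 was at 16.4, Sema3c at 221 and Ly6a at 147 CPM. In inflammation 4, Gbp9 was at 3.93, Itgam at 67.7, Psat1 at 65.1, Hoxc11 at 10.1 and Adamts1 at 164 CPM. In homeostasis 1, Egln1 was at 103 CPM, and in homeostasis 2 Myh3 was at 8.34, Col1a2 at 6430 and Lmod1 at 46.8 CPM.

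Other splits of the libraries were counted for each number of genes. For inflammation against homeostasis, 1 of 35 splits, the real one, gave 5602 genes or more, and the highest other gave 0. For resolution against homeostasis it was 1 of 35, with 8025 genes and 921 in the highest other. For resolution against inflammation it was 1 of 35, with 2431 genes and 1121 in the highest other, but these libraries were treated as paired and most splits put both libraries of a pair on one side. The 8 splits that part all 4 pairs, where the highest other gave 0, are too few for a share under 5%. The persistent (4668), returned (261) and resolution-alone (829) genes were each matched by 1 of 100 splits of the 12 libraries, the real one, with 0, 1 and 0 in the highest other, though these splits ignored the pairing. A class needs calls in 2 comparisons, and splits that mix the groups widen the spread within them. Such classes were thus almost bound to be empty, and no conclusion on their size is drawn from these splits. For the 2 counts against homeostasis, the real grouping gave more genes than any other split counted. If the libraries of a group came from 1 culture, such splits cannot exclude chance differences between cultures. They also say nothing about sex or other differences that follow the groups.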

How the results depend on the processing

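Left out X, Y and mitochondrial genes, homeostasis pairs as sole controls, GC and length offsets and the block in the paired groups alone were chosen after seeing the data. The 6 gene counts stayed within 1.5 times their value with RLE or upper-quartile factors, DESeq2, no low-count filter, the 12-library replicate block, GC and length offsets, and without X, Y and mitochondrial genes. A filter of 10 CPM in 4 libraries, which tests fewer genes, gave 3548, 5171 and 1600 genes for inflammation and resolution against homeostasis and resolution against inflammation, 3078 persistent, 114 returned and 534 in resolution alone, and r = 0.848 between the effects. Adding a 2-fold minimum gave 2082, 3530, 806, 1613, 165 and 237, and an adjusted p under 0.01 gave 3570, 1018, 3012, 154 and 351 (6109 for resolution against homeostasis, within 1.5 times). Voom with quality weights gave 7405 for resolution against inflammation, 697 returned and 2800 in resolution alone. Homeostasis 1 and 2 as the sole controls gave 407 returned, and homeostasis 3 and 4 gave 1257 in resolution alone. The block in the 8 paired libraries gave 4808 for resolution against inflammation, and 3697 with offsets. Controls divided 2 and 2 gave r = 0.609, 0.679, 0.702, 0.689, 0.711 and 0.656, with fewer controls per comparison. For the others the cause was not tested.

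Leaving out 1 library gave 4476 to 6076, 7090 to 8510 and 1242 to 4191 genes in the 3 comparisons, 3834 to 4875 persistent, 184 to 381 returned and 339 to 1645 in resolution alone. Of 390 gene results, 390 kept direction and side of the threshold with DESeq2 and with RLE factors, and over the 12 omissions of a library 4587 were kept, 27 gained a call and 66 lost one. Of 99 list results, 99 did with RLE or upper-quartile factors, and 70 with an estimated correlation. With fry 72 were kept, 23 gained a call and 4 lost one. The estimate reversed for Hoxd11 in resolution against homeostasis with GC and length offsets (-0.089, adjusted p = 0.635) and for Tnip1 in resolution against inflammation with the block and offsets (0.222, adjusted p = 0.0353), and the cause was not tested. Depth limits statements on genes at 0, where 3 counts allow 0.086 to 0.166 CPM per library.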

Other observations

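Among the tests in this part, those with GC and length offsets and with homeostasis pairs as the sole controls were chosen after the result was seen, as was the block in the 8 inflammation and resolution libraries. Of 13 genes of the mitochondrial genome, 8 rose and 0 fell in inflammation (9 and 0 adjusted over the list alone; camera adjusted p = 0.00881, adjusted p = 0.512 with an estimated correlation). In resolution 8 rose and 0 fell (the same adjusted over the list alone; 0.021, and adjusted p = 0.599 with an estimated correlation), a call lost without homeostasis 1 (0.0527) or homeostasis 4 (0.0579) and with homeostasis 1 and 2 as the sole controls (0.0517). COX1, a subunit of cytochrome oxidase, was at 3242 ± 355, 5416 ± 677 and 7319 ± 2029 CPM. Mitochondrial transcripts took 1.53%, 2.24% and 2.70% of counts in homeostasis, inflammation and resolution. The nuclear RNA Malat1 took 364 ± 250, 1128 ± 774 and 1957 ± 1180 CPM, and 18860, 19740 and 20420 genes on average had counts above 0. These means were lowest in homeostasis and highest in resolution, Malat1 overlapped between libraries of the groups, and the cause was not tested. Between resolution and inflammation 0 of the 13 passed in edgeR (0.678 and 0.967).

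Of 11 endothelial markers, 1 rose and 3 fell in inflammation (the same adjusted over the list alone; camera adjusted p = 0.275, 0.512 with an estimated correlation), with the adhesion protein gene Cdh5 at 3.13 ± 1.30, 0.457 ± 0.243 and 0.477 ± 0.306 CPM. That list passed without inflammation 1 (0.0466), 2 (0.0308) or 4 (0.0353) and without resolution 1 (0.0394), 3 (0.0415) or 4 (0.0313). In resolution 2 rose and 3 fell against homeostasis (0.315 and 0.546), and 2 rose and 0 fell against inflammation (0.913 and 0.967). Of 9 pericyte and smooth muscle markers, 1 rose and 3 fell in inflammation, 1 and 5 in resolution, and 0 and 4 between them (camera adjusted p = 0.179, 0.103 and 0.28). Among lining fibroblast markers the lubricin gene Prg4 went from 3212 ± 1216 to 829 ± 89.6 and 983 ± 398 CPM. Of these 13, 3 rose and 5 fell, 4 and 6, and 2 and 2 in the 3 comparisons (camera adjusted p = 0.351, 0.681 and 0.62). Of 22 sublining markers, 7 rose and 8 fell in inflammation and 10 and 9 in resolution (0.662 and 0.769), with the guidance factor Sema3c at 49.6 ± 12.9, 181 ± 27.0 and 334 ± 83.0 CPM.

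Lists that moved in mixed or small ways follow with genes up and down in inflammation, in resolution and between them. Wnt and Notch genes (37 tested) had 6 and 10, 10 and 12, and 5 and 4 (camera adjusted p = 0.496, 0.769 and 0.867), bone remodelling genes (15) 6 and 5, 6 and 5, and 1 and 1 (0.772, 0.769 and 0.987), and immediate early genes (26) 3 and 3, 4 and 7, and 1 and 4 (0.468, 0.315 and 0.28). Homeostasis 3 and 4 as the sole controls gave 0.0154 and 0.0144 for the last list in inflammation and resolution. Adipocyte markers (9) had 3 and 4, 4 and 1, and 4 and 1 (0.901, 0.327 and 0.15), and Apoe, a lipid carrier singled out after its values were seen, fell by 2.64 ± 0.20 SE in inflammation and by 1.39 ± 0.19 SE in resolution on the log2 scale. Epithelial markers (4) had 3 and 1, 2 and 1, and 1 and 1 (0.452, 0.811 and 0.688). Of 3 lymphocyte and neutrophil markers 2 rose in inflammation (camera adjusted p = 0.0389, adjusted p = 0.144 with an estimated correlation), a call lost without homeostasis 1 (0.0593), homeostasis 4 (0.0654) or resolution 2 (0.055), with homeostasis 1 and 2 as the sole controls (0.0834) and with GC and length offsets (0.0629). In resolution 1 rose, and between the groups 1 fell (0.492 and 0.249).

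The remaining comparisons of lists already described did not pass in camera. In inflammation these were matrix genes (10 up and 17 down, 0.123), which passed without inflammation 4 (0.0382), and cholesterol and fatty acid synthesis (8 and 0, 0.152), which passed with GC and length offsets (0.0315). In resolution against homeostasis they were proteases (8 and 10, 0.769), contractile genes (7 and 8, 0.769), senescence-associated genes (7 and 7, 0.769), oxidative stress genes (15 and 6, 0.103), cholesterol synthesis (5 and 16, 0.0833) and Schwann cell markers (2 and 5, 0.227). The oxidative stress list passed with GC and length offsets (0.024) and with homeostasis 1 and 2 as the sole controls (0.0183), and the cholesterol list with offsets (0.0398) and with homeostasis 3 and 4 (0.0457). In resolution against inflammation they were NF-kB genes (1 and 4, 0.69), complement (6 and 5, 0.987), cytokines (6 and 12, 0.187), senescence-associated genes (3 and 4, 0.913), oxidative stress genes (4 and 4, 0.678), the integrated stress response (2 and 8, 0.0692), chondrocyte markers (2 and 1, 0.481) and skeletal muscle markers (0 and 4, 0.108). Cytokines passed without inflammation 2 (0.0477) and with the block and offsets in the 8 libraries (0.0292), and the integrated stress response without inflammation 3 (0.0353), resolution 1 (0.0431) or resolution 2 (0.0491). Skeletal muscle markers passed without homeostasis 1 (0.0427), inflammation 3 (0.0304) or resolution 4 (0.0329).

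The test fry called further lists that camera did not. In inflammation these were cholesterol synthesis (up, 0.00801), sublining (down, 0.0152), endothelial (down, 0.00801), pericyte (down, 0.013) and adipocyte markers (up, 0.00057). In resolution against homeostasis they were oxidative stress genes (up, 0.00023), cholesterol synthesis (down, 0.00103) and sublining markers (up, 0.0335). Endothelial (down, 0.00569), pericyte (down, 0.000282), adipocyte (up, 8.08e-06), Schwann cell (down, 1.29e-05) and lymphocyte and neutrophil markers (up, 0.0013) were called there too. Between resolution and inflammation they were the integrated stress response (down, 0.0389) and pericyte (down, 0.0492), skeletal muscle (down, 0.00186), adipocyte (up, 0.00112) and lymphocyte and neutrophil markers (down, 0.023).

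For some lists the median, the mean and the direction of camera had different signs. In inflammation sublining markers had a median of 0.04 and a mean of -0.14 with camera down, bone genes 0.19 and -0.001 with camera up, and adipocyte markers -0.30 and -0.31 with camera up. In resolution against homeostasis these were contractile genes (-0.19 and 0.09, down), lining markers (0.06 and -0.19, down), bone genes (0.26 and -0.06, up) and limb genes (0.09 and -0.11, down). Between resolution and inflammation they were complement (0.04 and -0.25, up), secreted factors (-0.03 and -0.01, up), bone genes (-0.01 and -0.05, up), senescence-associated genes (0.12 and 0.12, down) and epithelial markers (-0.38 and 0.03, down). Of 33 lists, camera called 17, 13 and 11 with the preset correlation and 7, 3 and 2 with an estimated one.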
